A study of Synechocystis sp. PCC 6803 with 9 samples.

How the data were processed

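RNA was measured by strand-specific, rRNA-depleted, paired-end sequencing in 9 cultures of the cyanobacterium Synechocystis sp. PCC 6803, 3 given the solvent DMSO and 3 each given 1 µM or 3 µM of compound 4k. The design text describes the 3 replicates of each treatment as independent biological replicates. The length of exposure and the growth conditions are not given in the sources used here.

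The authors deposited 1 table of read counts per gene, with 1 column per library and 3594 genes. Per the submitters' processing notes, Trimmomatic and edgeR were used. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. All 32346 deposited counts are even numbers, so each read pair appears to add 2 counts. In the table, 12 rows are identical in all 9 libraries to an earlier row, and 11 of these lie 52 rows after their twin, so the reads of a repeated stretch appear to be counted for both copies. Whether the counting used strand is not given, so reads of antisense or overlapping genes cannot be told apart here.

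The deposited table names genes only by locus tags that begin with KBZ93_RS and does not pair them with gene names. None of these tags (0 of 3594) occurs in the reference gene table, which describes another assembly of this species. Gene names, coordinates and products are therefore not used here. Neighbouring genes are consecutive rows of the table. The numbers in the tags rise in 3591 of the 3593 steps from row to row, but whether row order is genome order is not given in the sources used here. The planned tests of gene lists need those names and were not run, and the parts of the rule for named genes that rest on function or list membership were not applied. Only 4 locus tags are printed. Other genes are described by their rank or by their row in the deposited table.

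The deposited counts summed to between 6153316 and 12918824 per library, that is 3076658 to 6459412 read pairs, with a median of 150 to 250 counts per gene. Genes with low counts were left out by edgeR's filterByExpr, which kept 3395 genes and dropped 0.0071% of all counts. Libraries were scaled with TMM factors, which ran from 0.622 to 1.58. The main test was edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) on the deposited counts, with all 9 libraries in 1 fit, treatment as the only factor and 6 residual degrees of freedom, and with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05, and a second count required in addition a change of at least 2-fold. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. CPM values are counts relative to the TMM-scaled library size, given as mean ± SD with n = 3 per group. Intervals of count ratios are exact 95% intervals on read pairs. A gene with no counts in a group was set against a floor of 3 read pairs (6 counts) over that group. These intervals and floors cover counting error only.

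The design of the tests, the alternatives and the rule for singling out genes were fixed before the data were examined, except where said otherwise. The rule took called genes with a mean count of at least 50 whose 3 treated libraries all lay on one side of the 3 reference libraries, and ranked them by fold change (6 per direction against DMSO, 5 per direction between the doses). The 2 genes called at 1 µM meet the rule and are printed with their tags, as are the 2 largest rises at 3 µM. Transcripts described by their abundance rank and runs of consecutive rows fall outside this rule and were chosen after their values were seen. The position of each library between the DMSO mean and the 3 µM mean was the least-squares coefficient of its log2 CPM (prior count 2), less the DMSO mean, on the difference between the 3 µM and DMSO means over 2822 genes with a mean count of at least 50.

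No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom of read pairs between libraries of 1 group was at least 8.87.

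The test was checked on simulated counts drawn with the DMSO means and the libraries' sizes and dispersions. Of 3395 genes 200 were changed, none of them among the lowest in DMSO. For the comparison of 3 µM with DMSO the test recovered 33% of 2-fold and 88% of 4-fold changes, with 8 false calls among 129. Without 1 µM replicate 3, whose spread enters the shared dispersion, the same simulation on 3431 genes recovered 86% and 100%, with 8 false calls among 194.

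Alternatives were edgeR's RLE, upper-quartile and unadjusted total-count scaling, DESeq2 (1.42.0), limma-voom (3.58.1), 2 other filters on low counts, a fit of only the 2 groups compared, leaving out the 20 most abundant genes, a replicate block and leaving out each library. Halving all counts and keeping identical rows once were added after seeing the data. Figures were drawn with matplotlib 3.10.9.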

Results

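Gene expression was profiled in Synechocystis sp. PCC 6803, a unicellular cyanobacterium with oxygenic photosynthesis, to ask how cells respond to 4k, an aminopyrimidine hydrazine compound studied for the control of cyanobacteria. Cultures received DMSO, 1 µM 4k or 3 µM 4k, with 3 libraries each. Total counts were 10492768 to 12918824 in the DMSO libraries, 7246280 to 11271162 at 1 µM and 6153316 to 8002996 at 3 µM. The deposited table does not pair its locus tags with gene names, so genes are described here by abundance, fold change and neighbourhood.

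The DMSO libraries resembled each other closely across 2822 genes, with Pearson's r of log2 CPM from 0.985 to 0.987, and so did the 3 µM libraries, with r from 0.987 to 0.989. Genes are not independent replicates in these correlations. The library labelled 1 µM replicate 3 stood apart from its group. Its r was 0.876 and 0.831 with 1 µM replicates 1 and 2, against 0.968 to 0.97 with the 3 DMSO libraries. Those 2 replicates had an r of 0.948 with each other, below the values within the DMSO and 3 µM groups. With the 3 µM libraries, replicate 1 had an r of 0.942 to 0.945 and replicate 2 of 0.919 to 0.927. On a scale where the DMSO mean is 0 and the 3 µM mean is 1, 1 µM replicates 1 and 2 lay at 0.664 and 0.786 and replicate 3 at -0.0108. DMSO libraries lay between -0.0231 and 0.0352 and 3 µM libraries between 0.993 and 1.01.

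**Figure D1:**
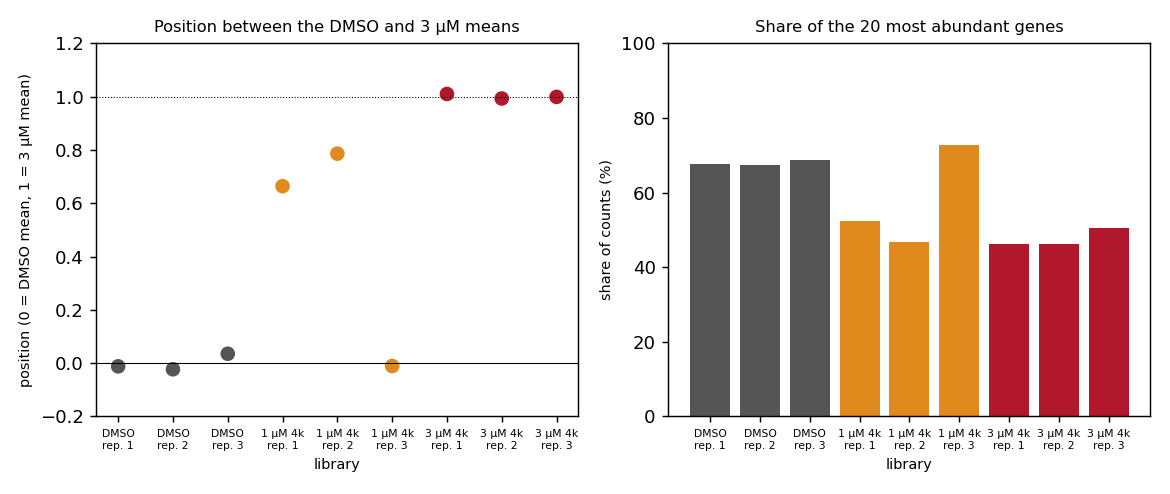
Left, the position of each library (1 point each) between the DMSO mean (0) and the 3 µM mean (1) over 2822 genes; right, the percentage of each library's counts in the 20 genes with the highest mean count, as bars. The library labelled 1 µM replicate 3 lies at -0.0108 and 72.8%, beside the DMSO libraries, whose shares are 67.3% to 68.7%.

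At 3 µM 4k, 33.4% of the genes tested differed from DMSO. Of 3395 genes tested, 527 rose and 606 fell, and 289 and 391 of these changed at least 2-fold (edgeR's quasi-likelihood test, adjusted p below 0.05). The median called rise was 1.06 and the median called fall -1.26 on the log2 scale, and 26 genes rose and 68 fell by 8-fold or more. All 3 libraries of one group lay beyond all 3 of the other for 62.3% of genes, where chance gives 10%. The median gene changed by 0.065 on the log2 scale under TMM, by 0.19 under upper-quartile scaling, where 689 genes rose and 495 fell, and by 1.2 under total counts, where 2039 rose and 157 fell. With any single DMSO or 3 µM library left out, 522 to 691 genes were called. Without 1 µM replicate 3, whose spread enters the shared dispersion, 802 genes rose and 818 fell. A fit of the DMSO and 3 µM libraries alone called 937 and 936.

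Under TMM scaling, falls at 3 µM were frequent among the transcripts most abundant over all libraries. Among the 20 genes with the highest mean CPM over the 9 libraries, 10 fell, none rose and 10 were not called; without 1 µM replicate 3, 16 fell and 1 rose. Among the top 100, 40 fell and 10 rose, so that 40% of them fell against 17.2% of all other genes (two-sided Fisher's exact test across genes, which are not independent replicates, p = 1.55e-07), whereas under total counts 41 of the 100 rose and 24 fell. The ranking matters, since a gene's change helps to decide its rank. Of the top 100 by mean CPM in DMSO, 53 fell and 5 rose, of those by mean CPM at 3 µM 22 fell and 16 rose (22% against 17.7% of the others fell, p = 0.288 by Fisher's exact test), and of those by the mean of both group means of log2 CPM 37 fell and 11 rose. These 3 rankings were added after the values were seen. Relative to the median gene, a difference that the choice of library scaling leaves nearly fixed by construction, the median log2 change was -1.65 for the top 20 and -0.6 for the top 100 by the 9-library ranking, but -1.93 and -1.32 by the ranking in DMSO, -0.93 and 0.19 by that at 3 µM and -1.42 and -0.51 by that on both group means. Under total counts alone 7 of the top 20 fell and 4 rose. The 20 genes with the highest mean count took 67.9% ± 0.721 of all counts in DMSO and 47.6% ± 2.42 at 3 µM (SD, n = 3 each).

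The transcripts ranked 2 and 3 by mean CPM over the 9 libraries come from neighbouring rows. The first of these fell from 186000 ± 11600 CPM in DMSO to 12700 ± 864 CPM at 3 µM (SD, n = 3; log2 fold change -3.87, SE 1.08, adjusted p = 0.0252 by edgeR), and the other from 172000 ± 7420 to 12000 ± 772 CPM (-3.84, SE 1.11, adjusted p = 0.0279 by edgeR). The transcript ranked 4 fell from 111000 ± 2490 to 28100 ± 2980 CPM (adjusted p = 0.0393 by edgeR). These 3 lost their call when any single DMSO or 3 µM library was left out, with adjusted p of 0.0573 to 0.132 by edgeR. Without 1 µM replicate 3, whose spread enters the shared dispersion, all 3 passed. Their adjusted p by edgeR was then 7.21e-07, 7.47e-07 and 3.07e-05 for ranks 2, 3 and 4. The transcript ranked 1 had 229000 ± 15800 CPM in DMSO and 135000 ± 23600 CPM at 3 µM, which did not pass the test (adjusted p = 0.371 by edgeR; 0.0358 without 1 µM replicate 3, with a log2 fold change of -0.76 in both fits; 0.19 to 0.587 with any other single library left out). As a share of the unscaled counts the transcript ranked 1 went the other way. It held 14.6% to 17.4% of each DMSO library and 18.5% to 22.9% of each 3 µM library. The 6 largest falls ranked by the rule had log2 fold changes of -5.18 to -4.62. The largest was a transcript of 3240 ± 457 CPM in DMSO and 89 ± 18.4 CPM at 3 µM (SE 0.645, adjusted p = 0.00103 by edgeR), and it passed in each fit that left out a single library. In contrast, 3 of the 6 lost their call when any single 3 µM library was left out, and also without single DMSO libraries except for 1 of them without DMSO replicate 3 (adjusted p of 0.0511 to 0.111 by edgeR). These 3 lie in rows 355, 356 and 359, within the longest run of falling rows described below. Without 1 µM replicate 3 all 3 passed (adjusted p of 4.43e-06 to 2.18e-05 by edgeR).

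The largest rises at 3 µM were of transcripts nearly undetected in DMSO. The 6 largest reached means of 10.4 to 41.8 CPM, had at most 4 read pairs in the 3 DMSO libraries together, and 4 of the 6 came from consecutive rows. KBZ93_RS17325, 1 of those 4, had no counts in DMSO and 41.8 ± 13.9 CPM at 3 µM (SD, n = 3), 172 times the floor of 3 read pairs over the DMSO libraries (adjusted p = 0.022 by edgeR). The exact 95% interval of its ratio to DMSO began at 139. At 1 µM its libraries held 0, 39.6 and 2.28 CPM. Its adjusted p at 3 µM by edgeR was 0.0508 to 0.061 when any single DMSO or 3 µM library was left out, and 0.00249 without 1 µM replicate 3. KBZ93_RS17600 had 2 read pairs in DMSO and 465 at 3 µM, a ratio of 187 (exact 95% interval 51.6 to 1550; adjusted p = 0.00993 by edgeR). KBZ93_RS17600 and 1 other of the 6 passed in each fit that left out a single library.

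**Figure D2:**
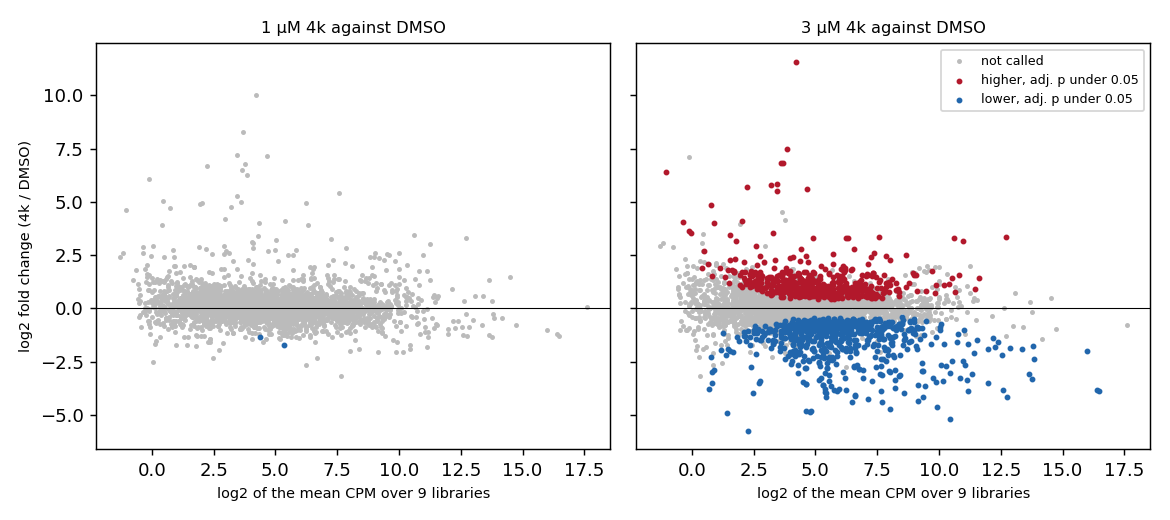
Log2 fold change against DMSO (y) by log2 of the mean CPM over the 9 libraries (x) for 3395 genes, at 1 µM (left) and 3 µM (right), with called genes in red (higher) and blue (lower). At 1 µM 2 genes were called; at 3 µM 527 were higher and 606 lower, by TMM-scaled counts.

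Part of the changes at 3 µM lay in runs of consecutive rows of the table. With identical rows kept once, 12 runs of at least 5 rows were called in 1 direction, and held 84 of 1126 called genes (7.46%). In 1000 shuffles of the calls there were at most 4 runs, with at most 21 genes. In the longest run, 21 consecutive genes fell, with log2 fold changes of -1.62 to -5.75 and a median of -3.39, from a median of 72.2 CPM in DMSO. Another 9 consecutive genes with a median of 2110 CPM in DMSO fell, with a median log2 fold change of -3.27. A run of 5 genes with a median of 14400 CPM fell, with a median of -3.64. Of the 12 runs, 2 were of rising genes and the others of falling genes.

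**Figure D3:**
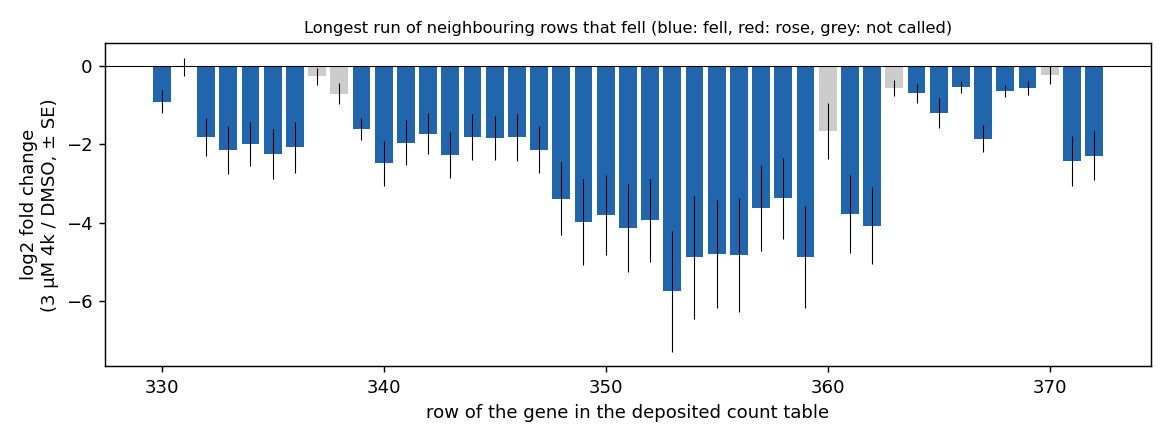
Log2 fold change (bars, ± SE) of 3 µM 4k over DMSO for the genes in rows 330 to 372 of the deposited table (x). Of the 43 genes, 37 fell (blue), none rose and the others were not called (grey).

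At 1 µM, 2 of 3395 genes passed the test, and both fell. KBZ93_RS00685 went from 80.9 ± 14.3 CPM in DMSO to 24.4 ± 4.7 at 1 µM and 16.1 ± 2.27 at 3 µM (SD, n = 3 each), with a log2 fold change of -1.73 at 1 µM (SE 0.211, adjusted p = 0.0257 by edgeR) and -2.33 at 3 µM (adjusted p = 0.000423 by edgeR). KBZ93_RS14100 went from 38.3 ± 4.99 to 15 ± 0.911 and 9.19 ± 0.833 CPM, with log2 fold changes of -1.35 (SE 0.166, adjusted p = 0.0257 by edgeR) and -2.06 (adjusted p = 0.000317 by edgeR). Both were lower than every DMSO library in all 3 libraries at 1 µM, replicate 3 included, which the rule for singling out genes requires. With any single library other than 1 µM replicate 3 left out, neither passed the test (adjusted p of 0.0624 to 0.222 by edgeR), and without replicate 3 both passed it. At an unadjusted p below 0.05 there were 629 genes, where 170 are expected by chance, and DESeq2 called 201 genes, 126 higher and 75 lower. In contrast, with all libraries kept, neither gene passed under total counts (adjusted p = 0.101 and 0.13 by edgeR), with a replicate block (0.103 and 0.178) or in a fit of the DMSO and 1 µM libraries alone (0.215 for both). Each of these fits called 0 genes.

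The count at 1 µM rested on replicate 3. Without the library labelled 1 µM replicate 3, 505 genes rose and 497 fell, 264 and 287 of them at least 2-fold. That comparison has 2 libraries at 1 µM, with an r of 0.948 between them, and leaves out a library chosen after its values were seen. In replicates 1 and 2 the transcript ranked 2 had 18100 and 11700 CPM, against 198000 in replicate 3 and 186000 ± 11600 in DMSO. The 21 consecutive genes that fell at 3 µM had a median log2 difference from DMSO of -3.65 in the mean of replicates 1 and 2 and of 0.149 in replicate 3. For the 9 consecutive genes the median difference was -2.2 in replicates 1 and 2 and -1.1 in replicate 3, while single DMSO libraries differed from the others by -0.19 to 0.262. None of these genes passed the test at 1 µM in the fit of all 9 libraries.

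Between the doses, 286 genes were higher and 344 lower at 3 µM than at 1 µM, 102 and 216 of them at least 2-fold (edgeR, adjusted p below 0.05). The 5 largest rises ranked by the rule were 1.75 to 1.99 on the log2 scale, and the 5 largest falls -3.11 to -3.88. The size of these falls depended on single libraries. In 4 of the 5 the highest value at 1 µM was that of replicate 3, and without it their log2 fold changes were -1.24 to -2.25. Of these 4, those in rows 3293, 3294 and 3295 are neighbours in 1 run of rows that fell at 3 µM. The fall of -3.88 rested on 1 µM replicate 2 (309 CPM, against 13.9 and 13.1 in replicates 1 and 3), without which it was -0.83 (adjusted p = 0.0889 by edgeR). Without 3 µM replicate 2 each of the 5 falls lost its call (adjusted p of 0.0534 to 0.14 by edgeR), as did 2 of the 5 rises (0.0539 and 0.0595). The log2 fold change of KBZ93_RS14100 between the doses was -0.71 (adjusted p = 0.0218 by edgeR; 0.0536 to 0.0858 without any single 3 µM library), and that of KBZ93_RS00685 was -0.6 (adjusted p = 0.075 by edgeR). The median gene moved by -0.089 on the log2 scale under TMM, by 0.028 under upper-quartile scaling, where 373 genes were higher and 275 lower, and by 0.54 under total counts, where 621 were higher and 60 lower. A fit of the 1 µM and 3 µM libraries alone called 112 and 128, and with any single 3 µM library left out 143 to 220 genes were called. Among genes changed at least 2-fold the split was 102 to 216, and 166 to 175 under upper-quartile scaling. Without 1 µM replicate 3 the direct comparison called 383 genes higher and 536 lower at 3 µM.

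The changes at both doses were compared across 3395 genes. Pearson's r of the log2 fold changes was 0.703, against a mean of 0.501 and a maximum of 0.564 in 100 simulations of unchanged groups that share the DMSO libraries. The covariance was 0.652 against a simulated 0.0897. The r came closer to its simulated values without 1 µM replicate 2, at 0.552 against a mean of 0.445 and a maximum of 0.529 (covariance 0.428, simulated 0.0719), and was 0.608 without replicate 1 (mean 0.446, maximum 0.513). Both genes called at 1 µM were also called at 3 µM in the same direction, where independent lists would share 0.357. Without 1 µM replicate 3, r was 0.786 (simulated mean 0.449) and the covariance 1.05 (simulated 0.0535). There 324 genes rose and 414 fell at both doses, and 20 changed in opposite directions. Independent lists of these lengths would share 118 in each direction. Of the 505 genes that rose at 1 µM in that fit, 165 were lower at 3 µM than at 1 µM by the direct test and 43 were higher. Of the 497 that fell, 105 were lower at 3 µM and 66 higher. The 2 libraries at 1 µM that chose these genes also entered the direct test, which favours values nearer to DMSO at 3 µM. The 165 and the 66 are therefore no measure of a response that peaks at 1 µM. The simulations shared at most 1 call, but with at most 4 calls per comparison they had few to share, so that number is no measure of agreement. The 3 DMSO libraries could not be split with 2 on each side. Part of the excess in r and in shared calls may therefore come from the shared controls. The differences of covariance, 0.562 and 0.992, subtract a simulated size of that part. The simulations drew all groups with 1 dispersion per gene, which the spread of 1 µM replicate 3 enters where it is kept. The simulated r and covariance therefore need not hold for the DMSO libraries of the data.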

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

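The test of the difference between the doses was planned, and among its alternatives halved counts and identical rows kept once were chosen after seeing the data. The change of KBZ93_RS14100 against DMSO differed between the doses by the direct test of 3 µM against 1 µM, by -0.71 on the log2 scale (SE 0.168, adjusted p = 0.0218 by edgeR), with all 3 libraries at 3 µM (8.44 to 10.1 CPM) below all 3 at 1 µM (14 to 15.7 CPM). The call was lost without any single 3 µM library (adjusted p of 0.0536, 0.0835 and 0.0858 by edgeR), with only the 2 groups compared (0.0745) and with the replicate block (0.0505). It was also lost under total counts (-0.1 on the log2 scale, adjusted p = 0.842 by edgeR). Over 21 alternatives the adjusted p ran from 0.00612 (DESeq2) to 0.842 (edgeR). Groups of 3 libraries are too small for the test for single outlying samples, and every deposited column was used in the comparisons.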

How the results depend on the processing

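Of the 4 genes followed singly, none had a called change that turned sign under an alternative. The split of all calls did turn: at 3 µM from 527 higher and 606 lower to 689 and 495 under upper-quartile scaling and 2039 and 157 under total counts, which shared 684 of the 1133 calls in the same direction. Halved counts and identical rows kept once were alternatives chosen after seeing the data. Under edgeR RLE scaling, upper-quartile scaling, limma-voom, both other filters on low counts, the 20 most abundant genes left out, halved counts and identical rows kept once, the numbers of changed genes, both directions together, stayed within 1.5 times their main values. Single directions moved more, as the 2-fold rises between the doses did under upper-quartile scaling (102 to 166). Under total counts only, the counts of changed genes became 0 at 1 µM (also 0 at 2-fold), 2196 at 3 µM (1907 at 2-fold) and, for the doses, 611 at 2-fold. Under that scaling the median log2 fold changes were 0.53, 1.2 and 0.54, against 0.054, 0.065 and -0.089 under TMM. DESeq2 called 201 genes at 1 µM, 124 of them at 2-fold, and the cause was not tested. With only the 2 groups compared in the fit, the counts were 0 at 1 µM (0 at 2-fold), 1873 at 3 µM, and 240 between the doses (172 at 2-fold); that fit leaves out the spread of the third group. The groups share replicate numbers, but libraries with the same number in different groups deviated from their group means with correlations of -0.11 to 0.047, so the numbers did not pair the libraries. Adding the replicate block gave 0 genes at 1 µM (0 at 2-fold), 984 at 3 µM and 364 between the doses; not every library correlated best with its own number.

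Leaving out single libraries gave 0 to 1002 genes at 1 µM (0 to 551 at 2-fold), 522 to 1620 at 3 µM (381 to 814) and 143 to 919 between the doses (120 to 481). At 1 µM the count was 1002 without 1 µM replicate 3, 1 without replicate 2 (another gene, which rose) and 0 without any other library. At 3 µM it was 584, 562 and 691 without DMSO replicates 1, 2 and 3, and 522, 527 and 553 without 3 µM replicates 1, 2 and 3. Between the doses it was 164, 143 and 220 without 3 µM replicates 1, 2 and 3. The smaller groups give these fits fewer libraries, and beyond that the cause was not tested. With all 9 libraries in the simulation, 33% of 2-fold changes at 3 µM were recovered, so small changes can be missed. The simulation changed 200 genes while 1133 were called in the data, so the 33% need not hold there. The r between the doses ran from 0.552 (without 1 µM replicate 2) to 0.786. The 2 falls at 1 µM kept their direction in 21 alternatives each and lost the call in 11, with adjusted p up to 0.222. The alternatives for tests of gene lists were not run, because the locus tags could not be paired with names.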

Other observations

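The tests on 1 µM replicate 3 and on the abundant transcripts were chosen after the results were seen; the tests on splits of the libraries and on neighbouring genes were written before their results were seen.

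Ranked by mean CPM over the 9 libraries, an order that differs within each group, transcripts 6 and 8 had the following values. Transcript 6 had 13600 ± 1670 CPM in DMSO (SD, n = 3), 36300, 17500 and 58000 CPM in the 3 libraries at 1 µM and 19300 ± 1560 CPM at 3 µM, and passed the test at neither dose (adjusted p = 0.17 and 0.435 by edgeR). Transcript 8 had 22900 ± 3620 CPM in DMSO, 12100, 14400 and 23600 CPM at 1 µM, and fell to 4390 ± 354 CPM at 3 µM (adjusted p = 0.00315 by edgeR).

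The library labelled 1 µM replicate 3 lay with the DMSO libraries. One explanation is the response of the other 1 µM libraries at 25% strength or more, through a lower exposure or mixed RNA. If scaled alike in every gene, it is argued against by the 69 genes that rose over 4-fold without this library. Replicate 3 reached a median of -0.0018 of their rise, with a 90th percentile of 0.13. Among the 106 genes that fell over 4-fold, however, the median was -0.12 and the 90th percentile 0.42. The 69 include genes that rose mainly in replicate 2, such as KBZ93_RS17600 with 1.16, 36.5 and 1.71 CPM in replicates 1, 2 and 3. For such genes a low value does not set replicate 3 apart from replicate 1. A lower exposure that acts unequally on genes was not tested. Replicate 3 was also not as alike to the DMSO libraries as these are to each other. The SD of its log2 difference from pairs of DMSO libraries was 0.513 to 0.528 against 0.319 to 0.338, a ratio of at least 1.52. An untreated library of another batch under a wrong label, and a 1 µM culture that had not responded, both stay open and cannot be told apart. The highest slope on the change in the other 1 µM libraries was 0.0114, below the 0.0416 of a DMSO library, and the labels give no batch. The 2 called genes and the run of 9 genes, chosen after their values were seen, were lower in this library too. As a set, 947 genes with a mean count of at least 50 were called without this library. Of these, 34 lay beyond all DMSO libraries and at least 2-fold from their mean in the same direction in replicate 3, and 28 in the opposite direction.

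The fall of abundant transcripts at 3 µM could come from scaling set by a few genes that hold most counts. With the TMM scaling taken from the genes other than the 20 most abundant and applied to all genes, log2 fold changes shifted by -0.035. By the ranking over the 9 libraries 10 of the top 20 and 41 of the top 100 then fell, while 0 and 10 rose. TMM by default leaves genes of extreme abundance out of its factors, so a small shift was set in advance. The test therefore cannot decide whether those 20 genes account for the fall. Total counts, of which these genes hold a large part, shift log2 fold changes by 1.1, and there 41 of the top 100 rose and 24 fell. Whether total RNA per cell changed was not measured, and the direction of change per cell stays open.

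Consecutive rows changed together at 3 µM: the log2 fold changes of 3225 pairs of consecutive rows had a Pearson's r of 0.484, with genes not independent replicates. Similar abundance of neighbours is argued against by shuffles within 10 classes of abundance, which reached at most 0.081 (permutation p = 1e-04, the smallest that 10000 shuffles can give). Replicate variation shared between neighbours was weaker, with an r of 0.075 to 0.15 for differences between DMSO libraries. If row order is genome order, which was not checked against a genome, co-transcription of neighbours is a hypothesis that may account for the pattern; reads that span neighbouring genes, or overlapping genes counted without strand, were not tested and stay open.

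Of the 10 splits of the 6 libraries of each comparison into groups of 3, 1 (the real one) gave as many calls as the real grouping, in each of the 3 comparisons with and without the 2-fold limit. The real counts were 2, 1133 and 630 (2, 680 and 318 at 2-fold) and the highest of any other split was 0. With 10 splits the share cannot be under 0.05. Every other split puts libraries of both treatments in 1 group, which raises the estimated spread where the treatments differ. Few calls there were therefore set in advance, and the 0 is no measure of calls by chance.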
